A study of Mus musculus with 8 samples.

How the data were processed

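Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on primary mouse podocytes, the epithelial cells that cover the glomerular capillaries of the kidney. Per the labels' protocols, kidneys were perfused with magnetic beads and digested for 20 min, glomeruli were collected on a magnet and digested for a further 45 min, and the cells were fixed in 1% formaldehyde, stained for podocin (the product of Nphs2) and sorted. The series holds 8 libraries, 2 each (replicates A and B) for H3K4me3, a mark of active promoters, H3K27me3, the mark deposited by Polycomb repressive complex 2, H3K4me1, a mark of enhancers, and input chromatin. Values from the H3K4me1 and input libraries were not analysed here.

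The data used are 2 peak lists, 1 for H3K4me3 and 1 for H3K27me3, each a combined list over the replicates of its mark. How the replicates were combined is not given in the sources used here. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic, Trim Galore 0.6.7, Bowtie2 2.5.1 and MACS2, and the build was mm10 (GRCm38). The role of each tool is not stated. Per the file headers, each row gives the position of a peak, its fold enrichment, its −log10 p-value and −log10 q-value, and the gene, transcript, distance to the transcription start site (TSS) and annotation class that the authors assigned. The fold enrichment is a ratio that the authors' peak caller computed for each peak and that the authors deposited, so it describes, ranks and filters peaks within a list only. Widths and other positions (bp) were deposited by the authors as start and end per peak.

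Both lists needed corrections before use. The column headed −log10(p-value) lay below the −log10 q-value in 99.3% of H3K4me3 rows but only 0.558% of H3K27me3 rows, while the column headed fold lay at or above it in 100% of rows of both lists, which a p-value and its own q-value require. In the H3K27me3 list the column headed fold also followed the rank of the −log10 q-value more closely than the other did (rank correlation 0.994 against 0.949 across peaks, a comparison added after seeing the data). The 2 headers were therefore read as exchanged in both lists, on weaker grounds for H3K27me3, and every H3K27me3 fold rests on this reading. Start positions counted from 0 and are given here from 1. The H3K27me3 list was ordered by gene ID and broke off inside a row, so peaks assigned to later gene IDs are not held. Of the H3K4me3 peaks, 6.30% (3.64% of promoter peaks and 15.9% of all peaks outside promoters) were assigned to gene IDs past that point, and H3K27me3 counts are too low by an unknown part of that order. Removing 2 duplicate rows left 17012 H3K27me3 peaks, and no H3K4me3 row was removed. Spreadsheet software had turned gene names into dates in 29 H3K4me3 rows and 21 H3K27me3 rows, and these rows entered peak counts but no gene count.

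Gene names were matched by symbol or synonym on the same chromosome to a RefSeq table of the same build, which gave biotype and gene ends but no strand. Of the rows, 95.3% (H3K4me3) and 93.1% (H3K27me3) matched. RefSeq 5′ ends lay within 1 kb of the files' TSS in 77.4% of 16569 rows (median distance 63 bp). No genome sequence or transcript annotation was used here. The design fixed for that case applied: a gene carried a mark when the authors assigned it a peak within 1000 bp of a TSS, and the background was the protein-coding genes named in either list, up to the last gene ID held (13440 genes). A gene with no peak of either mark assigned anywhere is missing from this background. All RefSeq protein-coding genes up to that ID (21699) were therefore added as a second background after the data had been seen, and unnamed genes count there as unmarked.

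The association of the marks across genes and the shares of gene lists were tested with Fisher's exact test (two-sided). List tests were adjusted by Benjamini-Hochberg over 16 lists times 3 marks (H3K4me3, H3K27me3, both). Overlap of the lists by at least 1 bp was compared with 1000 random placements of the H3K27me3 peaks within their chromosome, between the first and the last RefSeq gene (two-sided, smallest possible p 0.0020). The share of peaks within 1 kb of a RefSeq gene end was compared with 1000 placements (one-sided). Widths of the widest H3K4me3 promoter peak per gene, and the share of the gene plus 1 kb upstream covered by H3K27me3 peaks, were compared between list members and other genes with a permutation test of the difference of medians (100000 resamples, two-sided, smallest possible p 2.0e-05), adjusted over the lists with at least 5 members. The threshold was an adjusted p of 0.05. Shares of peaks have exact (Clopper-Pearson) 95% binomial intervals that cover counting error only. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with random seed 7.

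On simulated data, the H3K27me3 list test on 13440 genes recovered 91.25% of 160 lists of 20 genes made with 3 times the background share, and passed an unadjusted 0.05 in 6.88% of 160 unchanged lists. The H3K4me3 width test on 11816 genes recovered 100% of 40 lists of 20 genes with widths multiplied by 2, and passed 0.05 in 4.0% of 200 unchanged lists.

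The 16 gene lists, most tests, most alternatives and the rule for named genes were fixed before the data were examined. Outside that fixed design were the tests of podocyte genes among the widest peaks. The comparison of H3K4me3 width and fold between genes with both marks and genes with H3K4me3 only was outside it as well. The lists are podocyte structural genes, podocyte transcription factors, endothelial, mesangial and stromal, proximal tubule, distal tubule and collecting duct, immune, parietal epithelial, nephron progenitor, transcription factors of other lineages, Hox genes, Wnt and Fgf ligands, cell cycle genes, cyclin-dependent kinase (CDK) inhibitors, housekeeping genes and olfactory receptors. The nephron progenitor list shares Wnt4 and Fgf8 with the ligand list, Hoxa11 and Hoxd11 with the Hox list and Pax2 with the parietal list. The tests of these lists are therefore not independent. The rule names 10 genes always (Mafb, Wt1, Nphs1, Nphs2, Podxl, Synpo, Magi2, Lmx1b, Tcf21, Foxc2). For each mark it adds the 8 genes with the widest and the 5 with the highest-fold promoter peak. It also adds the 8 genes with the largest length covered by both marks within 5 kb of the TSS and, per list, up to 3 members with the widest peak of the mark the list was described for and up to 2 without it. It took 99 genes, and the text gives those that bear on each comparison. Any other gene named in the text was chosen after its values were seen.

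With 1 combined list per mark there is no value per replicate, so no replicate error, no test between replicates and no sequencing depth could be given. Alternatives covered the promoter window, the fold, width and q of peaks, the overlap rule, the placement of random peaks, the TSS used, the background and the measures of width and coverage.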

Results

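The genome-wide distribution of H3K4me3 and H3K27me3 was described in mouse podocytes sorted on podocin, from 1 combined list of peaks per mark over 2 libraries. The series title places these marks in a study of how MAFB, a podocyte transcription factor, permits binding of WT1 to podocyte promoters. All cells belonged to a single sorted population, so the comparisons are between marks and between groups of genes. The depth of the libraries is unknown and no replicate error can be given. The p-values below are taken over genes or random placements, which are not biological replicates, and they describe these lists only.

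H3K4me3 was concentrated at promoters in wide peaks, and most H3K27me3 peaks, as called, were short and lay outside promoters. The H3K4me3 list held 18845 peaks covering 24.4 Mb, with a median width of 1172 bp (quartiles 727 and 1654 bp) and a median fold enrichment of 21.9, as the authors' peak caller gave it. The H3K27me3 list, of which the last part is missing, held 17012 peaks covering 8.32 Mb, with a median width of 312 bp (quartiles 181 and 580 bp) and a median fold of 3.62. Many H3K27me3 peaks lay less than 3 kb apart, as around Isl1. Their widths are therefore those of single called peaks and do not give the extent of H3K27me3 regions. Promoters, within 1 kb of a TSS, held 78.2% of H3K4me3 peaks (14738, 95% interval 77.6 to 78.8%) and 29.4% of H3K27me3 peaks (5000, 28.7 to 30.1%). H3K4me3 promoter peaks had a median width of 1316 bp against 661 bp elsewhere. Of the H3K27me3 peaks, 35.5% were distal intergenic and 24.8% intronic. By RefSeq gene ends, 66.7% of H3K4me3 peaks lay within 1 kb of an end of a protein-coding gene against 5.04% after random placement. The values for H3K27me3 were 23.4% and 3.94% (one-sided permutation p = 0.0010 for both, the smallest possible). Only 62.1% of the H3K27me3 peaks (10559) had a q-value of at most 0.05, whereas all H3K4me3 peaks did. No H3K27me3 peak was listed on chromosome X or Y.

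Genes that define the podocyte carried some of the widest H3K4me3 peaks in the genome. Wt1, which encodes the zinc finger transcription factor required for podocyte development, had the widest promoter peak of all protein-coding genes. This peak measured 11476 bp (mm10, chromosome 2, 105122727 to 105134202), spanned the TSS and had a fold of 33.5. It was followed by Aopep (11367 bp), the angiogenic growth factor gene Vegfa (10245 bp), Synpo (10217 bp), which encodes the actin-associated protein synaptopodin, Nphs2 (9274 bp), which encodes the slit diaphragm protein podocin, the scaffold gene Magi2 (8544 bp), Hoxa10 (8031 bp) and Tns2 (7719 bp), which encodes a tensin. The peak at Nphs2 lay on chromosome 1 from 156309731 to 156319004, and that at Synpo on chromosome 18 from 60603341 to 60613557. The peaks at Aopep and Synpo lay at a TSS far inside the gene and not at its RefSeq 5′ end. At Synpo 0 bp of H3K4me3 lay within 5 kb of that end. The peaks at Magi2, Hoxa10 and Tns2 did not reach the RefSeq 5′ end either. Foxc2 ranked 10 (7379 bp), Podxl, the gene of the glycocalyx protein podocalyxin, 29 (6257 bp), Tcf21 38 (6045 bp), Mafb 47 (5654 bp), Lmx1b 66 (5278 bp) and Nphs1, which encodes nephrin, 116 (4618 bp) among 11968 ranked genes. At Mafb the peak ran from 160361391 to 160367044 on chromosome 2 and ended 21 bp inside the TSS, and a second peak of 2175 bp (160367242 to 160369416) lay upstream of the TSS. None of these 10 podocyte genes (Wt1, Synpo, Nphs2, Magi2, Foxc2, Podxl, Tcf21, Mafb, Lmx1b and Nphs1) had an H3K27me3 promoter peak. The only H3K27me3 peak assigned to any of them was a distal one of 303 bp at −22797 bp from the TSS of Mafb.

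**Figure D1:**
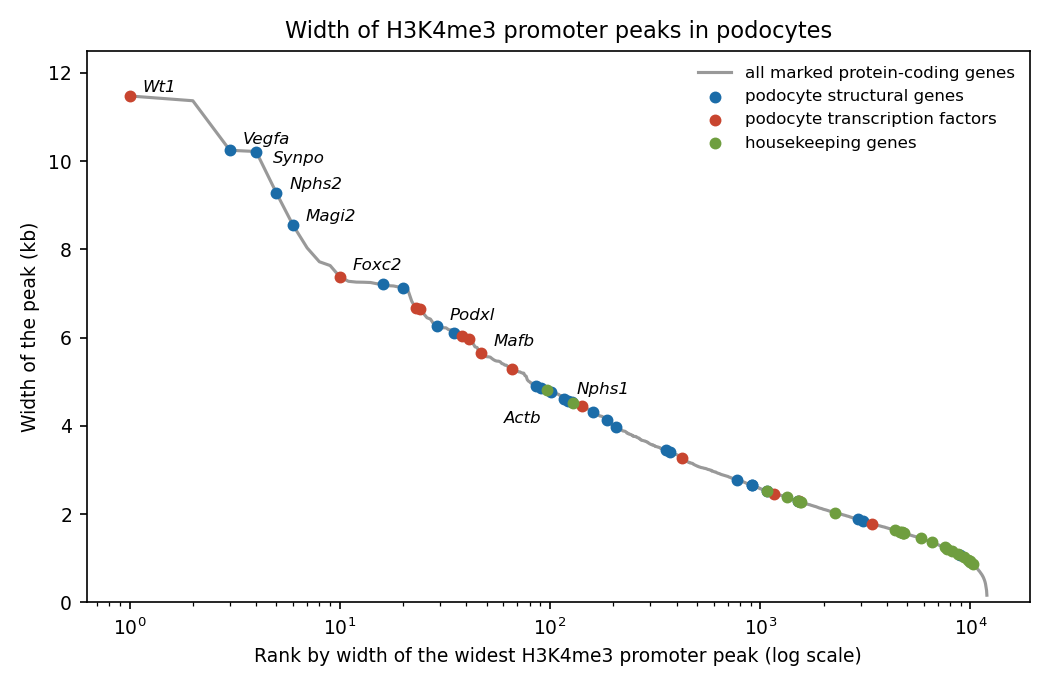
Width in kb of the widest H3K4me3 promoter peak of each protein-coding gene (vertical axis) against its rank (horizontal axis, log scale), with all 11968 marked genes as a grey line. Blue points are podocyte structural genes, red points podocyte transcription factors and green points housekeeping genes, and 6 of the 10 widest peaks belong to podocyte genes, whereas the housekeeping genes have a median of 1576 bp.

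As groups, both podocyte lists had wider H3K4me3 peaks than the other marked genes. The 27 marked structural genes had a median width of 4539 bp (quartiles 2716 and 6180.5 bp) against 1433 bp for the other 11789 genes, and 26 of them lay above the median of the others. The 13 transcription factors had a median of 5654 bp (quartiles 3266 and 6649 bp), and all 13 lay above the median of the others. Each difference had an adjusted p of 1.2e-04, which rests on the smallest raw p the permutations can give (2.0e-05). Of the 50 widest peaks, 15 belonged to the 40 marked podocyte genes, and of the 100 widest, 18 did (Fisher's exact test, p = 7.5e-27 and 7.7e-28). Nephron progenitor genes (median 2124 bp, permutation test, adjusted p = 0.0128), Hox genes (1924 bp, adjusted p = 0.00288) and CDK inhibitors (2329 bp, adjusted p = 0.0342) were also wider, by smaller amounts. With peaks at or above the median fold the Hox genes passed again (permutation test, adjusted p = 0.00424), and the other 2 lists had too few members left to be tested. With summed widths the CDK inhibitors did not pass (permutation test, adjusted p = 0.0615). The lists that did not pass were housekeeping (1576 bp, permutation test, adjusted p = 0.425), endothelial (1655 bp, 0.422), parietal epithelial (1687 bp, 0.433), other-lineage (1279 bp, 0.433), Wnt and Fgf (1388 bp, 0.744), mesangial (1086.5 bp, 0.110) and cell cycle genes (1149 bp, 0.110). Fold did not follow width at every gene. The highest-fold promoter peaks were at Hnrnpu (fold 62.5, 3933 bp), an RNA-binding protein gene, Gm3448 (58.4, 637 bp), Phf10 (54.4, 2022 bp), Il17rd (54.0, 1066 bp) and Brwd1 (52.8, 2553 bp). The peak assigned to Gm3448 lay outside the RefSeq gene of that name.

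The widest H3K27me3 promoter peaks were found at Sim1 (9409 bp, chromosome 10, 50892231 to 50901639), Pitx2 (9229 bp), Isl2 (9082 bp), Gdf6 (7054 bp), Pou3f3 (7034 bp), Fezf1 (6964 bp), Nkx2-3 (6316 bp) and Dmrt3 (6122 bp). Except for Gdf6, which encodes a secreted growth factor, all encode transcription factors, and none is in the gene lists. Their folds lay between 3.80 and 4.29. The promoter peaks of highest fold were at Sox11 (6.05), Prox1 (5.70), Cebpa (5.50), Lef1 (5.27) and Izumo1 (5.24). H3K27me3 covered a median of 54.4% of the gene and its 1 kb upstream at 27 transcription factors of other lineages. The medians were 31.0% at 6 CDK inhibitors, 14.4% at 15 nephron progenitor genes, 9.98% at 38 Wnt and Fgf ligand genes and 0.872% at 38 Hox genes, against 0% for other genes (permutation, adjusted p = 8.0e-05 for each list but the CDK inhibitors, where it was 1.9e-04). Coverage was also above that of other genes at 10 distal tubule (3.61%, permutation test, adjusted p = 0.00228), 5 proximal tubule (3.08%, 0.0359), 17 endothelial (2.30%, 3.2e-04) and 13 mesangial genes (1.91%, 0.00228). The coverage test held only genes named in either list, so list members with no assigned peak were left out. A gene without an H3K4me3 peak entered only through an assigned H3K27me3 peak, which favours coverage by construction. Any coverage was found at 7 of the 10 distal, 5 of 5 proximal, 11 of 17 endothelial and 9 of 13 mesangial genes tested. The full lists hold 18 distal, 17 proximal, 20 endothelial and 18 mesangial genes, and medians over all of them were not computed. These 4 differences therefore cannot be read as higher coverage of the full lists. The median was 0% in both podocyte lists and in the immune, parietal, cell cycle, housekeeping and olfactory lists, as in other genes, so the test of medians says nothing about lower or equal coverage there.

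**Figure D2:**
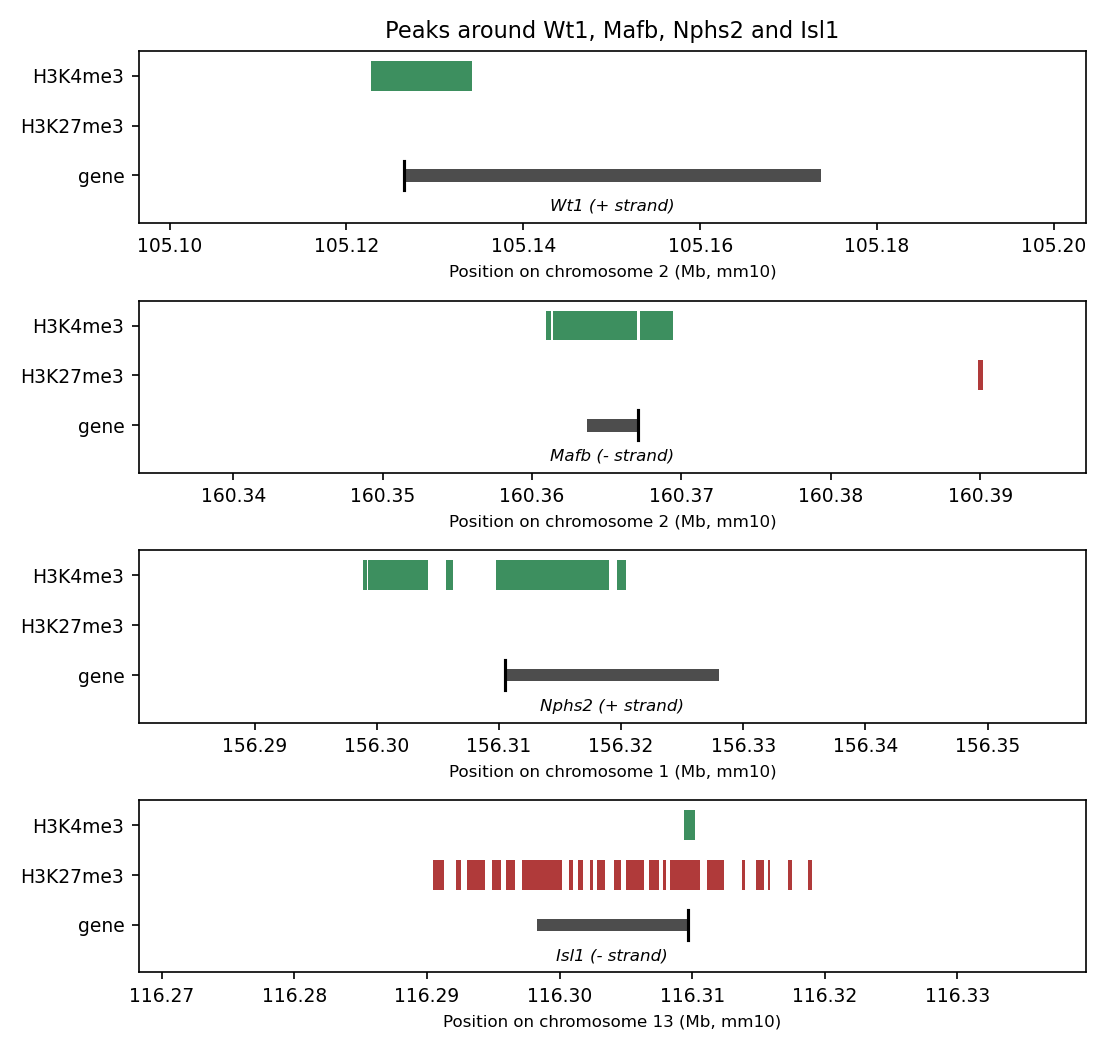
Peaks of H3K4me3 (green) and H3K27me3 (red) and the RefSeq gene (grey bar, black line at its 5′ end) around Wt1, Mafb, Nphs2 and Isl1, with position in Mb of mm10 on the horizontal axes. Wt1 and Nphs2 show H3K4me3 alone, Mafb shows H3K4me3 and a distal H3K27me3 peak of 303 bp, and Isl1 has 21 H3K27me3 peaks and an H3K4me3 peak of 879 bp.

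In the full lists, most genes with H3K27me3 at the promoter also had H3K4me3. Among 13440 protein-coding genes named in either list, 9927 had H3K4me3 only, 1889 had both marks, 799 had H3K27me3 only and 825 had neither within 1 kb of a TSS. On the autosomes alone, 9537 genes had H3K4me3 only, since no H3K27me3 peak was listed on X or Y. Of the 2688 genes with H3K27me3, 70.3% also had H3K4me3 (16.8% when only peaks at or above the median fold of their list were counted), and 15.99% of the 11816 genes with H3K4me3 also had H3K27me3. In 1686 of the 1889 genes with both marks (89.3%) the promoter peaks overlapped. The largest lengths covered by both marks within 5 kb of the TSS that the authors assigned to the widest H3K4me3 promoter peak were at the transcription factor genes Bcl11a (4551 bp) and Gata2 (3533 bp), at Unc45b (3298 bp), which encodes a myosin chaperone, and at Pax2 (3273 bp), Sox11 (3245 bp), Uncx (3205 bp), Nr2f1 (3119 bp) and Insm1 (3031 bp). At Bcl11a, Gata2, Unc45b and Pax2 this TSS lies inside the gene and not at its RefSeq 5′ end. Genes with both marks had narrower H3K4me3 peaks than those with H3K4me3 only (median 1109 against 1485 bp) and lower H3K4me3 folds (16.3 against 29.2; permutation p = 0.0010 for both, the smallest possible with 2000 resamples).

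Whether the marks attracted or avoided each other depended on the background. Among the genes named in either list, H3K27me3 was less frequent at genes with H3K4me3 than at those without (15.99 against 49.2%, odds ratio 0.196, Fisher's exact test p = 3.4e-179). This background leaves out genes with no peak at all. Among all 21699 RefSeq protein-coding genes, H3K27me3 was more frequent at genes with H3K4me3 (15.99 against 8.08%, odds ratio 2.16, Fisher's exact test p = 2.1e-71). By position, 2542 of the 18845 H3K4me3 peaks (13.5%) overlapped an H3K27me3 peak by at least 1 bp, against a mean of 239.3 (SD 15.2) after random placement, a ratio of 10.6 (two-sided permutation p = 0.0020, the smallest possible). That placement takes no account of the preference of both marks for promoters. In the other direction, 17.2% of H3K27me3 peaks overlapped an H3K4me3 peak.

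**Figure D3:**
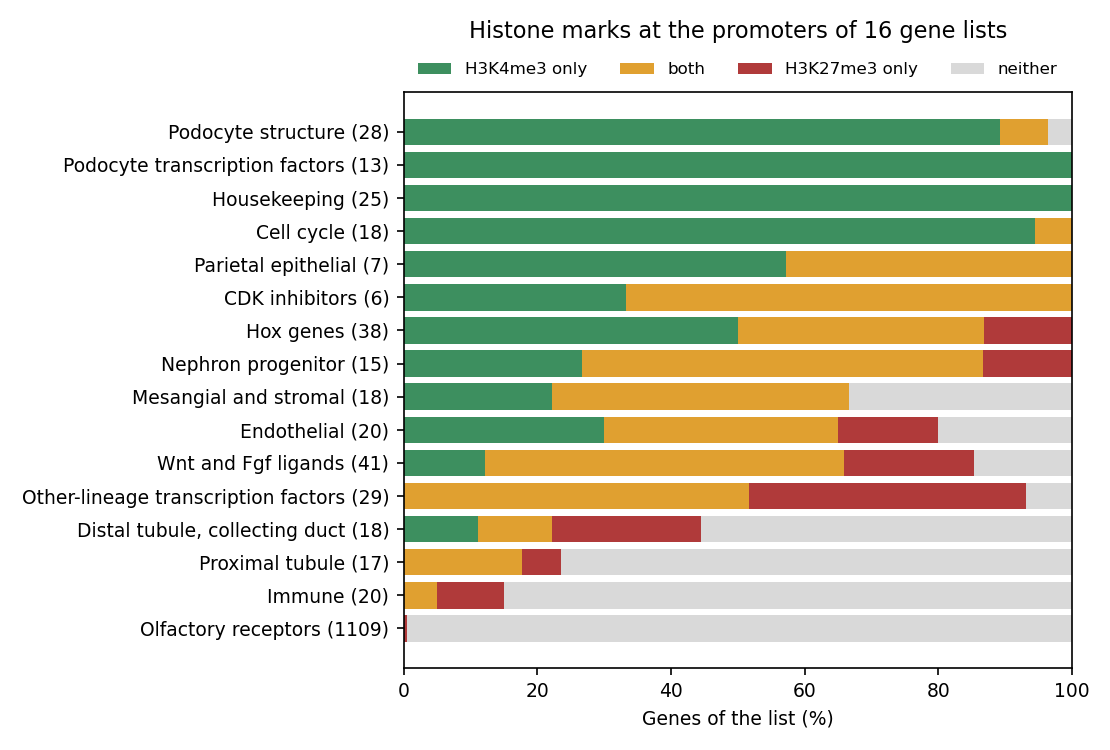
Share in percent (horizontal axis) of the genes of each list with H3K4me3 only, both marks, H3K27me3 only or neither at the promoter, with the number of genes assessed in brackets. All 13 podocyte transcription factors and all 25 housekeeping genes have H3K4me3 only, 27 of 29 other-lineage transcription factors have H3K27me3, and 1104 of 1109 olfactory receptor genes have neither. Genes on chromosome X, such as Hprt and Pgk1 of the housekeeping list, are included although no H3K27me3 peak was listed there.

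The gene lists separated along these classes. All 13 podocyte transcription factors and 25 of the 28 podocyte structural genes had H3K4me3 only at the promoter. Outside promoters, Hey1 had 1 H3K27me3 peak assigned (12.2% of the gene and its 1 kb upstream covered) and Clic5 had 17, none of them within the gene or its 1 kb upstream. Trpc6, a cation channel gene, and Arhgap24, a Rho GTPase activating protein gene, also had short H3K27me3 promoter peaks (120 and 189 bp). Col4a3, a collagen IV chain gene of the glomerular basement membrane, had no peak assigned to it. It overlaps the 5′ end of Col4a4, and the shared promoter region lay under the 7126 bp H3K4me3 peak assigned to Col4a4. All 25 housekeeping genes had H3K4me3 only, as did 17 of 18 cell cycle genes, Mki67 having both marks. The structural gene Col4a5 and the housekeeping genes Hprt and Pgk1 lie on chromosome X. No H3K27me3 peak was listed there, so the lists could not give these genes H3K27me3. Among the named genes the H3K4me3 share of these 4 lists did not pass the test (Fisher's exact test, adjusted p = 0.121, 0.491, 0.120 and 0.213 for structural genes, transcription factors, housekeeping and cell cycle genes), because 87.9% of the other genes had the mark. Against all RefSeq protein-coding genes, of which 54.4% had it, the shares were higher (Fisher's exact test, adjusted p = 4.5e-06, 0.00102, 1.6e-06 and 1.0e-04). Housekeeping genes had H3K27me3 less often than other named genes (0 against 20.0%, Fisher's exact test, adjusted p = 0.0141), which did not pass with the RefSeq background (adjusted p = 0.0974). For the podocyte lists a lower H3K27me3 share did not pass in either background. Among named genes it was 2 of 27 structural genes and 0 of 13 transcription factors (Fisher's exact test, adjusted p = 0.212 and 0.145). With the RefSeq background the adjusted p was 0.684 and 0.481 (Fisher's exact test).

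Regulators of other developmental programmes carried H3K27me3, in the full lists often together with H3K4me3. Of 29 transcription factors of other lineages, 15 had both marks and 12 had H3K27me3 only, while Myf5 and Gata1 had neither. When only peaks at or above the median fold of their list were counted, none kept both marks (−2.50 percentage points from other genes, against 41.6 in the full lists). Gata1 lies on chromosome X, where no H3K27me3 peak was listed. Examples were Gata6 (H3K27me3 peak 5118 bp, both marks), Pax6 (5019 bp, both) and the intestinal factor Cdx2 (4975 bp, H3K27me3 only). Of 41 Wnt and Fgf ligand genes, 22 had both and 8 had H3K27me3 only, with the widest peaks at Wnt7b (3365 bp), Fgf8 (2400 bp) and Wnt3 (2324 bp). Of 15 nephron progenitor genes, 9 had both marks, among them Six2 (H3K27me3 peak 4439 bp), which maintains the progenitor pool, and Pax2 (2708 bp). Cited1 and Eya1 were among the 4 with H3K4me3 only, and Cited1 lies on chromosome X as well. H3K27me3 was more frequent in each of these 3 lists than in other named genes (27 of 27 tested, 30 of 38 and 11 of 15, against 19.8 to 19.9%; Fisher's exact test, adjusted p = 2.9e-18, 1.3e-13 and 9.8e-05). Of 38 Hox genes, 19 had H3K4me3 only, 14 had both and 5 had H3K27me3 only (adjusted p for H3K27me3 = 1.8e-04), with wide H3K27me3 peaks at Hoxc13 (2600 bp), Hoxc12 (2570 bp) and Hoxd13 (2278 bp) and none at Hoxa1 or Hoxa10. The CDK inhibitors Cdkn1a, Cdkn2a, Cdkn2b and Cdkn2c had both marks, whereas Cdkn1b and Cdkn1c, which encode p27 and p57, had H3K4me3 only (4 of 6 with H3K27me3, Fisher's exact test, adjusted p = 0.0370). This call was lost with promoter windows of 500 bp (Fisher's exact test, adjusted p = 0.140) or 2.5 kb (0.0503), the 5′-most TSS (0.138) and peaks of at least 500 bp (0.0700). All 5 lists also passed for H3K27me3 with the RefSeq background (adjusted p between 1.1e-21 and 0.00573). H3K4me3 was less frequent than in other named genes at other-lineage factors (15 of 27, Fisher's exact test, adjusted p = 1.7e-04) and Wnt and Fgf ligands (27 of 38, 0.0125). Neither difference passed with the RefSeq background (Fisher's exact test, adjusted p = 0.910 and 0.224), where the sign for the ligands was opposite.

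Markers of the other glomerular cell types had mixed classes. Of 20 endothelial genes, 7 had both marks, 6 had H3K4me3 only, 3 had H3K27me3 only and 4 had neither. The vascular endothelial growth factor receptor gene Flt1 had both (H3K4me3 peak 2093 bp, H3K27me3 peak 2953 bp), Pecam1 had H3K27me3 only (380 bp) and Emcn had no peak assigned. Plat and Cldn5, however, had H3K4me3 only, in peaks of 7258 and 4320 bp, which ranked 12 and 159 by width. Of 18 mesangial and stromal genes, 8 had both, among them Gata3 and Tbx18, 4 had H3K4me3 only and 6 had neither, including Acta2 and Col3a1. Foxd1, a transcription factor gene of this list, had an H3K4me3 peak of 5969 bp (rank 40) and no H3K27me3. All 7 parietal epithelial genes had H3K4me3, and 3 of them also had H3K27me3. H3K27me3 was more frequent than in other named genes at endothelial (10 of 17 tested, Fisher's exact test, adjusted p = 0.00168) and mesangial genes (8 of 13, 0.00396), and with the RefSeq background as well (adjusted p = 1.3e-04 and 0.00173). For the parietal list it did not pass (Fisher's exact test, adjusted p = 0.212).

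Markers of tubules and of blood cells mostly had neither mark assigned at the promoter. No promoter peak was assigned to 13 of 17 proximal tubule genes, including Aqp1 and Cubn. The same held for 10 of 18 distal tubule and collecting duct genes, including Aqp2 and Atp6v0d2, and for 17 of 20 immune genes, including Adgre1. Peaks assigned to a neighbouring gene were not counted. Aqp2, however, had 5 H3K27me3 peaks assigned outside its promoter, and H3K27me3 covered 26.5% of the gene and its 1 kb upstream. H3K4me3 was found at the promoter of 3 proximal tubule genes (Lrp2, Ass1 and Slc27a2, all with H3K27me3), of 4 distal genes (the widest peak, 1132 bp, at Hsd11b2) and of 1 immune gene (Ikzf1, with H3K27me3). Against all RefSeq protein-coding genes these H3K4me3 shares were lower (17.6, 22.2 and 5% against 54.5%; Fisher's exact test, adjusted p = 0.00551, 0.0149 and 1.2e-05). Among the named genes the proximal tubule list did not pass for H3K4me3 (3 of 5 tested, Fisher's exact test, adjusted p = 0.188), while the distal (4 of 10, 0.00155) and immune lists did (1 of 7, 1.3e-04). H3K27me3 was more frequent than in other named genes at the proximal (4 of 5, Fisher's exact test, adjusted p = 0.0153) and distal lists (6 of 10, 0.0152). With the RefSeq background the proximal list no longer passed (4 of 17, Fisher's exact test, adjusted p = 0.219) and the distal list did (6 of 18, 0.0302). Of 1109 olfactory receptor genes, 5 had H3K27me3 and 1 of these, Olfr94, had both marks. With the RefSeq background their H3K27me3 share was below that of other genes (0.451 against 13.03%, Fisher's exact test, adjusted p = 1.7e-55), whereas among the 23 that were named in either list it did not pass the test (5 of 23, adjusted p = 0.875).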

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

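No paired analysis was possible because each mark has 1 combined list and no value per replicate, so leaving out replicates could not be run either. Not run were the background of CpG-rich promoters, which needs a genome sequence, and a change to the authors' gene assignment, which is already the one used. The RefSeq background, RefSeq gene ends and the q limit of 0.05 were chosen after seeing the data. The wider H3K4me3 peaks of both podocyte lists, and the overlap above random placement, kept their direction and side of the threshold under every alternative run for them. The ratio of observed to random overlap ranged from 3.94 (higher-fold peaks) to 37.1 (overlap of at least 50% of the H3K4me3 peak). Of the summary values under alternatives, 96 stayed on the same side or within 1.5 times, 36 moved and 2 reversed. For single lists, 374 values stayed, 36 lost and 19 gained significance and 33 reversed, most of them differences with an adjusted p above 0.05 both ways. Sequencing depth is not given, so how far it limits the lower H3K27me3 peaks is unknown.

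The association of the marks across genes reversed with the background: the odds ratio was 2.16 with all RefSeq protein-coding genes and 1.53 with any peak within 1 kb of a RefSeq gene end, against 0.196. The cause is the construction, since genes without any peak enter only the RefSeq background. With all RefSeq genes, 7 lists lay above other genes for H3K4me3 (5 with RefSeq ends) against 0, and 1 lay below for both marks (1 with RefSeq ends) against 0. Differences of list members from other genes that changed sign with all RefSeq genes were, in percentage points, 10.6 (endothelial), 32.2 (nephron progenitor), 32.4 (Hox) and 11.4 (Wnt and Fgf) for H3K4me3, −3.71 (immune) for both marks and −12.6 (olfactory) for H3K27me3. With RefSeq ends they were −7.11 (mesangial), 29.6 (nephron progenitor) and 21.9 (Hox) for H3K4me3, −1.38 and −2.52 (immune, H3K27me3 and both) and −11.5 (olfactory, H3K27me3).

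Keeping the peaks of each list at or above its median fold left 9426 H3K4me3 and 8506 H3K27me3 peaks, with 95.8 and 36.4% at promoters. It left 335 genes with both marks, 1658 with H3K27me3 only and 318 H3K4me3 peaks overlapping H3K27me3. For H3K4me3, 1 list lay above other genes and 10 below, for H3K27me3 0 below, and for both marks 2 above. Wider H3K4me3 was found in 3 lists (both podocyte lists and Hox genes), since nephron progenitor genes and CDK inhibitors had too few members left to be tested, and higher H3K27me3 coverage in 5. H3K4me3 peaks at genes with both marks have lower folds (median 16.3 against 29.2 at genes with H3K4me3 only), so this filter removes them first, and both marks at other-lineage genes rest on lower-fold H3K4me3 peaks. Signs changed for H3K4me3 at mesangial (−39.1 points) and parietal genes (−33.6), and for both marks at endothelial (−2.50), proximal (−2.49), distal (−2.49), parietal (−2.49) and other-lineage genes (−2.50). The width difference of Wnt and Fgf genes became 13 bp.

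Keeping peaks of at least 500 bp left 5122 H3K27me3 peaks, 82.8% of H3K4me3 and 45.4% of H3K27me3 peaks at promoters, 1173 genes with both marks, 508 with H3K27me3 only and 1514 overlapping H3K4me3 peaks. Then 0 lists lay below other genes for H3K27me3 and 5 above for both marks. H3K4me3 changed sign at mesangial (−8.84 points) and nephron progenitor genes (0.916), and the width difference of Wnt and Fgf genes became 34 bp (143 bp with summed widths). With at least 500 bp of the window covered, 1236 genes had both marks. An overlap of at least 50% of the H3K4me3 peak left 1484 H3K4me3 peaks. Merging peaks closer than 3 kb left 7720 H3K27me3 peaks, and q at most 0.05 left 10559, of which 34.9% lay at promoters.

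Promoter shares of H3K4me3 and H3K27me3 peaks were 76.3 and 21.9% at 500 bp, 81.7 and 43.8% at 2.5 kb, and 63.3 and 19.2% with the 5′-most TSS per gene. At 500 bp, signs changed for H3K4me3 at mesangial (−2.81 points) and parietal genes (−1.71) and for H3K27me3 at olfactory genes (−1.12). At 2.5 kb they changed for both marks at immune genes (−0.983) and H3K4me3 at Hox genes (0.703). With the 5′-most TSS they changed for H3K4me3 at podocyte structural (−0.588), mesangial (−12.9), parietal (−10.6) and nephron progenitor genes (4.603). Apart from the cases with a stated construction, the cause was not tested.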

Other observations

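The tests of the missing X peaks against the part of the list not held, of H3K4me3 spill, of chance overlap and of mixed cell types, and the Hox comparison, were chosen after the result was seen. The other tests below were written before.

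The Hox clusters differed by position within the cluster. Of 26 assessed genes of paralogue groups 1 to 9, 9 had an H3K27me3 promoter peak, against 10 of 12 genes of groups 10 to 13 (Fisher's exact test p = 0.0128, although neighbouring genes are not independent). In the Hoxa cluster all 8 genes of groups 1 to 9 had H3K4me3 only, as did Hoxa10, while Hoxa11 and Hoxa13 were covered by H3K27me3 over 72.9 and 53.8% of the gene and its upstream region. The Hoxc cluster had the same order, with H3K4me3 only at all 5 genes of groups 1 to 9 and at Hoxc10 and H3K27me3 at Hoxc11, Hoxc12 and Hoxc13. All 4 Hoxd genes of groups 10 to 13 had H3K27me3, at Hoxd10 only in a peak of 185 bp, and so did Hoxd1 (153 bp), 1 of the 4 genes of groups 1 to 9. In the Hoxb cluster 8 of 9 genes of groups 1 to 9 had an H3K27me3 promoter peak, of 77 to 578 bp, and coverage was 44.4% at Hoxb1 and 57.4% at Hoxb13, the single assessed gene of groups 10 to 13, so this cluster showed no clear order. The broadest H3K4me3 of any Hox gene lay at Hoxa10 (8031 bp) and Hoxa9 (6082 bp).

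Of the 50 widest H3K4me3 promoter peaks, 31 belonged to genes in none of the lists, and 2 of the 50, at Pde4b and Gnas, also had H3K27me3. Among the 31 were Smad7 (7171 bp) and Smad6 (6306 bp), which encode inhibitors of transforming growth factor beta and bone morphogenetic protein signalling, Ddn (5776 bp), which encodes dendrin, a slit diaphragm-associated protein, and Ezr (5916 bp), which encodes the membrane-cytoskeleton linker ezrin. H3K4me3 extended beyond the promoter at Podxl, with 6 further peaks covering 17908 bp, and Aopep had 9 further peaks covering 18538 bp. The genes with most H3K27me3 peaks assigned were Prdm16 (60), Pax3 (54), Tle3 (47), Pax7 (45), Dyrk2 (44) and Skap1 (44). The 20 H3K27me3 peaks of highest fold (7.51 to 24.5) had a median width of 104.5 bp, and 0 of them lay at a promoter. Among the CDK inhibitor genes, Cdkn2a, which encodes p16 and p19, had its widest H3K27me3 peak (2810 bp) at 89280366 to 89283175 on chromosome 4 and its widest H3K4me3 peak (1440 bp) at 89294262 to 89295701. The marks were not separate there, as promoter peaks of both overlapped and 1028 bp within 5 kb of the TSS assigned to the H3K4me3 peak carried both.

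The podocyte genes had H3K4me3 peaks 3161 bp wider in the median than other marked genes (40 genes). Across genes, width rose with fold (Spearman's rho 0.475 over 11816 genes, which are not independent replicates) and weakly with gene length (0.152), so fold or length could have set the width. Within 20 bins of similar fold, the 40 genes were still 3205.5 bp wider, and within 20 bins of similar gene length 3158 bp wider (permutation p = 2.0e-05 for both, the smallest possible). Neither the listed fold nor gene length therefore accounts for the difference. Whether the fold of a peak describes its highest point or its mean is not stated, so peak height itself was not matched and remains open. How the peak caller joined neighbouring regions was not tested. That broad H3K4me3 marks genes of podocyte identity is a hypothesis, found and tested on the same lists, and the sort on podocin gives no second cell type to compare with.

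H3K27me3 at H3K4me3 promoters could come from spill of strongly marked, open promoters into the H3K27me3 libraries, from chance, or from a mixture of cells. Spill would raise H3K27me3 with H3K4me3, but 0.876% of genes in the top decile of H3K4me3 fold had H3K27me3 against 58.7% in the bottom decile, a ratio of 0.0149. These values argue against spill as the main source only. The share would also fall if genes with H3K27me3 have weak H3K4me3, so spill at part of the promoters is not excluded. Genes with both marks were 1.29 times the number expected under independence among RefSeq genes. Among named genes the ratio was 0.799, which is lowered by construction, because genes with no peak are left out there. A background of CpG-rich promoters could not be run. Chance overlap of marks that both favour promoters therefore cannot be told apart from a real association. The overlap of 10.6 times the mean of random placement does not settle this, because that placement ignores the preference of both marks for promoters. A mixture would leave regulators of unrelated lineages without H3K4me3 only if the other glomerular cells lack the mark there, which these lists cannot show. Of these regulators, 51.7% had both marks, although none kept both when only peaks at or above the median fold were counted (−2.50 percentage points from other genes). The limits for this test were set after the share had been seen. The share therefore does not decide whether a mixture contributed at these genes. For the endothelial and mesangial lists (39.5% of 38 genes with both marks), a mixture of cell types and both marks on the same chromatin cannot be told apart, since the lists hold a single sorted population and no second cell type to set the marks against.

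No H3K27me3 peak was listed on chromosome X, where 795.2 would be found at the autosomal rate of 0.823 per protein-coding gene over 966 genes. H3K4me3 had 612 peaks there against 852.0. Its rate on X, 0.634 per gene, lay just below the range over single autosomes (0.665 to 1.03). The missing end of the list does not account for the absence of H3K27me3 peaks on X, because 98.0% of the X H3K4me3 peaks are assigned to gene IDs in the part held. Weaker signal on X is a candidate explanation: X promoter H3K4me3 peaks had a median fold of 16.1 against 25.9 on the autosomes, a ratio of 0.621. Scaled by that ratio, 0.241% of H3K27me3 peaks would keep a fold above the 5th percentile of the list (3.30), and 99.8% would stay above its lowest fold (1.57), so the effect depends on a threshold that the list does not show. Removal of X by the authors before deposit remains open and was not tested.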
